A study of Mus musculus with 33 samples.

How the data were processed

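The work uses the gene counts that the submitters supplied for regulatory T cells (Treg) of the mouse colon. The table holds raw counts for 53465 Ensembl genes, of which 53274 carry a symbol, in 33 columns, and each column matched 1 library. Its genome build is GRCm38. Submitters' notes name HTSeq 0.4.1, Picard 1.134, FastQC 0.11.3 and SAMtools 1.2. The aligner, the annotation release and the strand of the counts are not given in the sources used here. Gene positions, types and exons come from GENCODE M21. Reads were not analysed here.

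Each Treg library comes from 200 sorted cells, read as 58-base single reads. Cells were sorted as CD45+, TCR+, CD4+ and Foxp3+. From each of 8 mice, 4 gates were sorted by TSLPR (gene Crlf2) and ST2 (gene Il1rl1): 4 naive mice (mice 1 to 4) and 4 mice with colitis-associated cancer (mice 5 to 8), giving 32 Treg libraries in 8 groups of 4. There is also 1 library of naive CD44low Foxp3-negative T cells, reported as values only, whose mouse is not given in the sources used here. A mouse is the replicate. Whether the naive mice had a mock treatment, and whether naive and cancer mice were sorted and sequenced on the same days, is not given in the sources used here.

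The main test was the edgeR (4.0.16, R 4.3.3) quasi-likelihood F-test on counts, with TMM scaling, the filterByExpr gene filter (minimum count 10, minimum total 15), a robust fit and Benjamini-Hochberg (BH) adjustment with a limit of 0.05. A group-means model of all 32 Treg libraries tested 14861 genes for cancer versus naive within each gate, ST2+ versus ST2-, TSLPR+ versus TSLPR-, TSLPR+ST2- versus TSLPR-ST2+ and 3 interactions. For cancer versus naive per mouse, the 4 gates of a mouse were summed and 15338 genes were tested. Adjusted p values of genes are from this test unless another tool is named. Fold changes are model estimates, given as higher or lower. Averaged over groups on the log2 scale, they can differ from the ratio of the printed means. Counts per 1000000 (CPM) of named genes use TMM-scaled totals, and CPM of library measures (Epcam, Lyz2, Malat1 and the sort genes per library) use plain totals. Values after ± are standard deviations (SD) over libraries, or over mice for the per-mouse sums.

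The gates of a mouse share the animal, so residual sharing was measured once. Deviations of libraries from their group means, taken over genes, had a mean correlation of 0.0228 over 48 pairs from the same mouse. The 3 pairs over 0.1 were all from naive mouse 3 (0.339, 0.279 and 0.266, among its TSLPR-ST2-, TSLPR-ST2+ and TSLPR+ST2+ libraries). Pairs of different mice of the same status had a mean of -0.00757 over 144 pairs, with 1 pair over 0.1. The main model, fixed beforehand, has no mouse term, and fits with the mouse as a block and without mouse 3 are given as alternatives.

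Gene lists were tested with limma (3.58.1) camera on voom values with a preset correlation between genes of 0.01 and BH adjustment over the lists of a comparison. The 26 lists are Treg core, effector tissue Treg, colon Treg and Th17, naive and central T cell, Th1, Th2, inhibitory receptors and ectoenzymes, TNF receptor and CD28 family costimulation, tumour-infiltrating Treg, homing receptors, T cell receptor (TCR) activation, immediate early and heat shock, interferon response, proliferation, glycolysis, cholesterol synthesis, STAT5 targets, conventional helper cytokines, and markers of epithelial cells, B and plasma cells, macrophages and dendritic cells, neutrophils, mast cells, stromal and endothelial cells, CD8, NK and gamma-delta T cells, and Y-linked genes. Of these, 22 had enough tested members. Neutrophil, mast cell and stromal markers had 2 tested members each and Y-linked genes had 0. The immediate early and heat shock list was set up to show effects of dissociation. Camera was repeated with an estimated correlation, and the fry test was run beside it. For each list the members passing over all genes are given as higher or lower, followed by the count when p values were adjusted over the list alone.

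The comparisons, the main test, the lists, a set of alternative settings and the rule for naming genes were fixed before the data were examined. By that rule the text names Foxp3, Crlf2 and Il1rl1. It also names the 10 higher and 10 lower genes with the smallest p in each main comparison, with at least 10 CPM in the higher group, and 5 of each within gates. From each described list up to 4 members with the smallest p are named. Some genes that the rule picks are not reported here. Genes without an official name, pseudogenes, mitochondrial, ribosomal, immunoglobulin and TCR segment genes were counted but not named by rank. Those settings were relative log expression (RLE) size factors, DESeq2 (1.42.0), no low-count filter, each mouse left out, only the 8 libraries of a gate, limma-voom with the mouse as a random effect, the mouse as a block in edgeR, thinned libraries, and the mean of the 4 gate contrasts. A planned exclusion of libraries under 1000000 counts or with few detected genes removed 0 libraries. Added after the data were seen were fits without single libraries or without the TSLPR+ST2+ gate, fits with the log2 mitochondrial share or 3 marker scores (macrophage, B cell, epithelial) as covariates, and a contrast of the cancer effect in TSLPR+ST2+ Treg with the mean of the other 3 gates.

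Main counts were also compared with those from all 35 splits of the 8 mice into 4 and 4, or from 50 labellings of the gates within mice. On simulated counts with 100 genes changed 2-fold and 100 changed 4-fold, the main test recovered 44% and 78% for a within-gate comparison, and 79% and 99% for the per-mouse sums. False calls were between 2.87% and 9.93% of all calls over the 6 simulated comparisons. The simulation gave each gene the same spread in all groups and no mouse effect, so it cannot show false calls from unequal spread. In the data, mice of the cancer TSLPR+ST2+ group had Spearman correlations of 0.804 to 0.889 with each other, the lowest of the 8 groups. Of 98 genes named by rank or as sort genes, 23 have an exon that overlaps an exon of another gene with counts, among them Foxp3, Junb, Irf7 and Gapdh. Since the strand is not given, their values can include reads of the neighbour. Families with near-identical copies (H2-Q6, Ifi209, Phf11c, Ctla2a, Lilr4b) are uncertain for the same kind of reason.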

Results

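The series asks how TSLP and IL-33, read through their receptors TSLPR and ST2, relate to Treg in colorectal cancer progression. Colon Treg of Foxp3-YFP mice were sorted into TSLPR-ST2-, TSLPR-ST2+, TSLPR+ST2- and TSLPR+ST2+ gates. Cancer mice received azoxymethane (AOM, 10 mg/kg) and 3 cycles of dextran sulfate sodium (DSS, 7 days each), and were taken 2 weeks after the last cycle. No group received AOM or DSS alone, so effects of tumours, of recent colitis and of the chemicals cannot be told apart below. Library totals ran from 4038718 to 8839946 counts (median 6458270), with 14632 to 16845 genes detected. Y-linked genes had at most 1 count in a library, in 3 libraries.

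The sort genes follow the gates. Il1rl1, the ST2 receptor gene (chromosome 1, 40429570 to 40465415, + strand), averaged 181 ± 58.7 CPM in ST2+ libraries and 2.38 ± 3.21 in ST2- libraries (n = 16 each, higher in 8 of 8 mice, 76.3-fold, edgeR adjusted p = 4.71e-10). Crlf2, the TSLPR gene (chromosome 5, 109554709 to 109558993, - strand), averaged 40.4 ± 8.83 CPM in TSLPR+ and 15.8 ± 5.64 in TSLPR- libraries (higher in 8 of 8 mice, 2.62-fold, edgeR adjusted p = 1.10e-08). In the cancer mouse 5, however, Crlf2 was 30.0 CPM in the TSLPR-ST2+ library and 25.3 in the TSLPR+ST2+ library, against the order of the gates. Klrg1 in these 2 libraries was 172 and 843 CPM, against 184 to 238 and 672 to 757 CPM in the same gates of mice 6 to 8. Foxp3, the Treg lineage factor (chromosome X, 7573644 to 7595245, + strand), had 127 ± 39.7 CPM in ST2+ and 166 ± 39.2 in ST2- libraries (lower in 8 of 8 mice, 1.32-fold, edgeR adjusted p = 0.0240). It had 130.4 against 162 CPM in TSLPR+ and TSLPR- libraries and was also lower in 8 of 8 mice, but did not pass (edgeR adjusted p = 0.0622). Between cancer and naive mice Foxp3 passed in TSLPR+ST2+ Treg alone, at 90.8 ± 25.8 against 155 ± 35.4 CPM (n = 4 each, 1.70-fold lower, edgeR adjusted p = 0.0431). In the per-mouse sums Foxp3 (128 against 166 CPM, adjusted p = 0.155), Crlf2 (26.9 against 29.8, adjusted p = 0.598) and Il1rl1 (76.2 against 113, adjusted p = 0.246) did not pass.

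**Figure D1:**
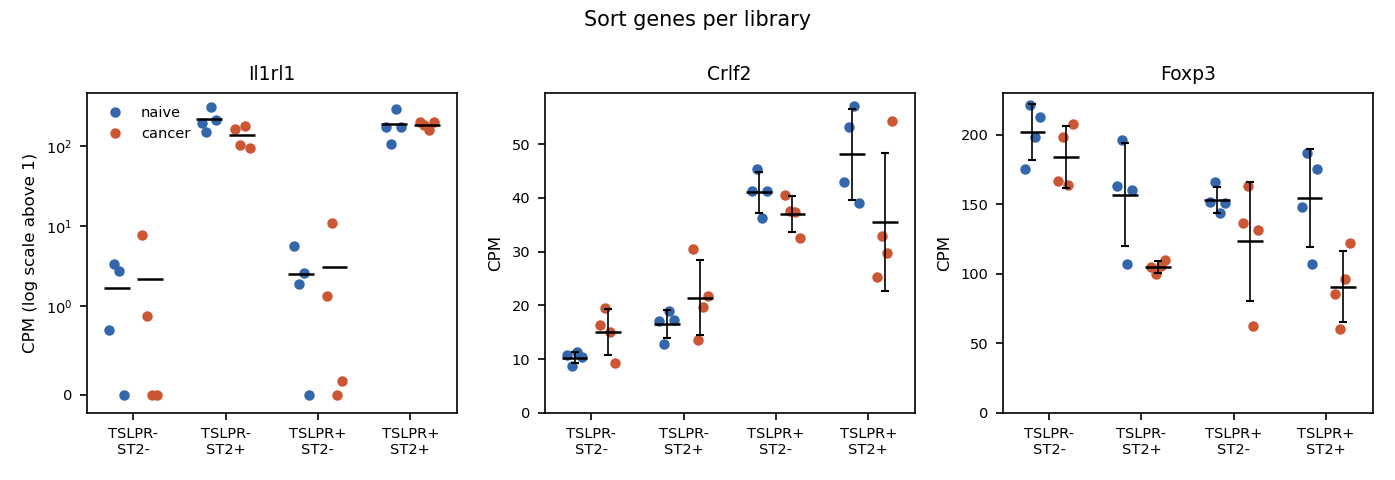
CPM of Il1rl1, Crlf2 and Foxp3 in each Treg library by gate (n = 4 mice per group, naive blue, cancer orange), bars are means, with SD for Crlf2 and Foxp3. Il1rl1 is on an axis that is linear near 0 and logarithmic above.

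In Treg of cancer mice, summed per mouse, 10 of 18 interferon list genes were lower, as were Junb, the chemokine receptor Ccr4 and the IL-2 receptor chain Il2ra. The interferon list lost its call with an estimated correlation (adjusted p = 0.0915). Irf7, the transcription factor that drives type I interferon genes (chromosome 7, 141262706 to 141266481, - strand), averaged 366 ± 33.3 CPM in 4 cancer mice and 640.3 ± 43.3 in 4 naive mice (1.75-fold lower, edgeR adjusted p = 0.00351). Oasl2, an interferon-induced sensor of viral RNA (chromosome 5, 114896936 to 114912234), fell 2.40-fold from 163 to 67.8 CPM (adjusted p = 0.00190). Ifit3, an interferon-induced antiviral protein, fell 2.01-fold from 308 to 153 CPM (adjusted p = 0.00512). Junb, an AP-1 subunit with a role in effector Treg (chromosome 8, 84974484 to 84978718, - strand), fell 1.90-fold from 751 ± 17.5 to 395 ± 36.0 CPM (adjusted p = 0.00190). Like Zfp36 below, Junb is on the immediate early and heat shock list, set up to show effects of dissociation. Whether dissociation adds to its fall was not tested. Ccr4, the receptor for CCL17 and CCL22, fell 1.96-fold from 96.8 to 49.4 CPM (adjusted p = 0.00294). Casp1, the inflammasome protease that matures IL-1 beta and IL-18 (chromosome 9, 5298517 to 5307265, + strand), rose 2.96-fold from 33.6 ± 3.05 to 99.3 ± 18.5 CPM (adjusted p = 0.00351).

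Further genes lower per mouse were Zfp36, an mRNA decay factor (1.54-fold), the peptide hormone gene Rln3 (2.07-fold), the lysosomal peptide transporter Abcb9 (1.80-fold), the mRNA-binding Igf2bp3 (7.49-fold, 2.19 against 16.5 CPM) and Phf11c (1.60-fold). Higher genes were the RNA helicase Ddx17 (1.91-fold, 133 against 69.9 CPM), the TCR adaptor Lat (1.31-fold) and the HSP90 co-chaperones Stip1 (1.32-fold), Chordc1 (1.28-fold) and Ahsa2 (1.57-fold). The receptor gene Lilr4b (2.73-fold), Vps13d (1.55-fold), the cathepsin inhibitor Ctla2a (2.62-fold) and the Cdc42 effector Cdc42ep3 (1.54-fold) rose as well. In all, 44 genes rose and 142 fell (186 of 15338), and 2586 had unadjusted p under 0.05 where 767 are expected by chance. Of 15 mitochondrial genes tested, 6 rose and 0 fell, and the mitochondrial share of the summed counts was 1.39 to 1.88% in cancer and 0.775 to 1.15% in naive mice. With its log2 as a covariate, added after the data were seen, edgeR called 0 genes (1346 with unadjusted p under 0.05). All 186 genes kept their sign, the median log2 fold kept 0.746 of its size and the median SE went from 0.10 to 0.18. With mice 1 to 8 left out in turn the count was 69, 37, 98, 38, 79, 28, 57 and 67. The calls of Lat, Stip1, Chordc1, Lilr4b, Vps13d, Ctla2a, Cdc42ep3 and Ahsa2 were lost in at least 1 of these fits, with Ahsa2 reaching adjusted p = 0.0959 without mouse 4.

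Among lists tested per mouse, 10 were lower and each lost the call with an estimated correlation. Interferon response fell, with the smallest p at the preset correlation (camera adjusted p = 4.43e-16) but not with an estimated correlation (adjusted p = 0.0915). Here 10 of 18 genes fell, 8 did not pass, and 14 were lower when adjusted over the list alone, among them Mx1 (34.3 against 100.3 CPM, 2.92-fold, adjusted p = 0.0161). Treg core fell (camera adjusted p = 8.96e-06, adjusted p = 0.0525 with an estimated correlation) with 3 of 13 genes lower and 10 not passing (9 lower when adjusted over the list alone). The 3 were the peptide receptor Gpr83 (286 against 473 CPM, 1.65-fold), Il2ra (413 against 627, 1.52-fold) and Lrrc32, which presents latent TGF-beta (170.2 against 336, 1.97-fold). STAT5 targets fell (camera adjusted p = 5.34e-05, adjusted p = 0.0525 with an estimated correlation), with 2 of 10 lower, 8 not passing and 4 lower adjusted over the list alone, Il2ra and the cytokine signalling inhibitor Socs2 (94.3 against 147 CPM). Immediate early and heat shock genes fell (camera adjusted p = 0.000237, adjusted p = 0.0525 with an estimated correlation). Junb and Zfp36 fell, 11 did not pass, and adjusted over the list alone 6 were lower and 2 higher. Proliferation fell (camera adjusted p = 8.96e-06, adjusted p = 0.203 with an estimated correlation) with the replication helicase gene Mcm2 lower (90.5 against 142 CPM), 17 not passing and 9 lower adjusted over the list alone.

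Smaller per-mouse list results follow. Th2 fell (camera adjusted p = 0.000765, adjusted p = 0.203 with an estimated correlation) with Ccr4 lower, 4 not passing and 2 lower adjusted over the list alone. Cholesterol synthesis fell (camera adjusted p = 0.00586, adjusted p = 0.203 with an estimated correlation) with 2 lower, among them the sterol desaturase gene Sc5d, 12 not passing and 2 lower adjusted over the list alone. Effector tissue Treg fell (camera adjusted p = 0.0162, adjusted p = 0.203 with an estimated correlation) with Prdm1, which encodes Blimp-1, lower (41.7 against 73.4 CPM), 18 not passing, and 5 lower and 1 higher adjusted over the list alone. TCR activation (camera adjusted p = 0.0222, adjusted p = 0.203 with an estimated correlation) and TNF receptor and CD28 family costimulation (camera adjusted p = 0.0299, adjusted p = 0.191 with an estimated correlation) fell without a member passing over all genes (13 and 8 not passing). Adjusted over the list alone, 3 and 1 of their members were lower and 1 TCR activation gene was higher. Macrophage and dendritic markers were not called (camera adjusted p = 0.496), though Cd68 (17.7 against 42.3 CPM) and the complement gene C1qb (45.0 against 98.4) fell, 12 did not pass, and 5 were lower and 3 higher adjusted over the list alone.

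**Figure D2:**
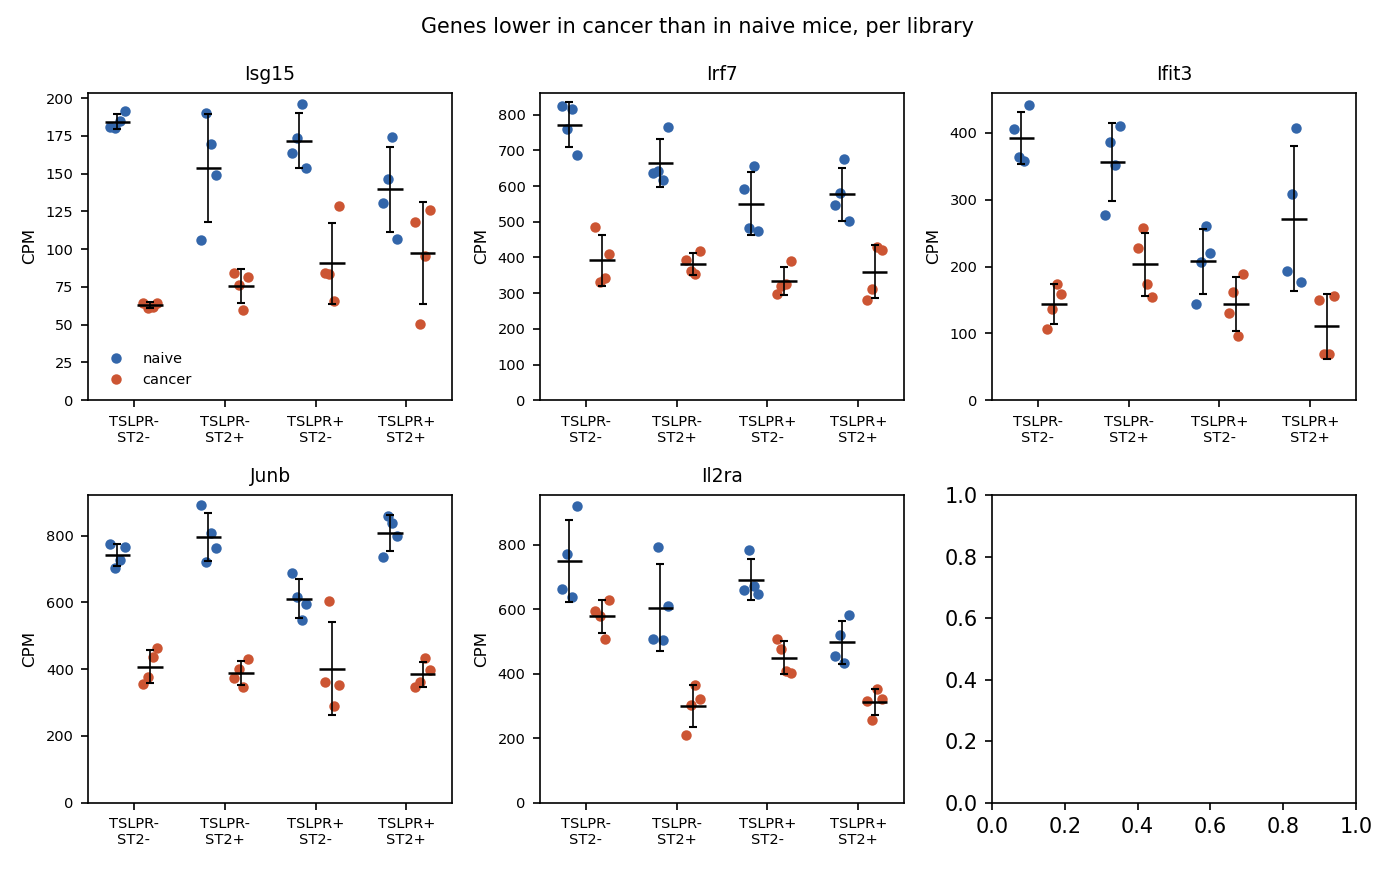
CPM of Isg15, Irf7, Ifit3, Junb and Il2ra by gate in naive (blue) and cancer (orange) mice, with each library as a point (n = 4 mice per group, mean ± SD).

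Within TSLPR-ST2- Treg interferon genes were again lower in cancer, with 6 list members among the 22 genes that fell. Isg15, a ubiquitin-like interferon product (chromosome 4, 156199424 to 156200818), fell 2.92-fold from 184 ± 5.10 to 63.1 ± 1.81 CPM (n = 4 each, edgeR adjusted p = 0.000629). Irf7 fell 1.97-fold (772 to 392 CPM, adjusted p = 0.000629) and the antiviral gene Rsad2 fell 5.11-fold (102 to 20.0 CPM, adjusted p = 0.00418). Junb (1.82-fold) and the DNA-sensing family gene Ifi209 (1.47-fold) also fell. The nonclassical class I gene H2-Q6 (1.45-fold), Casp1 (4.61-fold), the muscle gene Ttn (4.01-fold), Stip1 (1.37-fold) and the tetraspanin Cd9 (1.66-fold) rose. Interferon response fell (camera adjusted p = 3.34e-25, adjusted p = 0.00199 with an estimated correlation) with 6 of 18 lower, 12 not passing and 14 lower adjusted over the list alone. Treg core (camera adjusted p = 0.00139, 13 not passing, 1 lower adjusted over the list alone) and STAT5 targets (camera adjusted p = 0.000528, 10 not passing, 2 lower adjusted over the list alone) fell and were kept with an estimated correlation. Homing receptors fell (camera adjusted p = 0.0333, adjusted p = 0.0966 with an estimated correlation, 18 not passing, 1 lower adjusted over the list alone). Immediate early and heat shock genes fell by the test (camera adjusted p = 0.00220, adjusted p = 0.0966 with an estimated correlation, Junb lower, 13 not passing, 3 lower adjusted over the list alone), while their mean log2 change was 0.02 and the median -0.40. In all 9 genes rose and 22 fell, and the count was 13, 14, 24, 13, 18, 15 and 11 without mice 1 to 7. Casp1, Cd9, Stip1 and Ttn lost the call in some of these fits, with Casp1 at adjusted p = 0.0892 without mouse 3 and 0.0995 without mouse 7.

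In TSLPR-ST2+ Treg, Il2ra and the Treg gene Gpr83 fell with cancer beside Junb. Il2ra, the high-affinity IL-2 receptor chain, went from 604 ± 135 to 300.0 ± 65.1 CPM (n = 4 each, 2.01-fold lower, edgeR adjusted p = 0.00204). Gpr83 went from 560.3 ± 68.4 to 247 ± 28.0 (2.27-fold lower, adjusted p = 0.00825) and Junb from 796 ± 72.5 to 388 ± 36.3 (2.05-fold lower, adjusted p = 0.000590). Irf7 (1.74-fold) and Ifi209 (1.42-fold) fell. Lat (1.44-fold), Ddx17 (1.93-fold), the adhesion protein gene Emb (1.64-fold), and the neighbouring inflammatory caspases Casp4 (44.0 against 7.92 CPM, 5.55-fold, adjusted p = 0.0279) and Casp1 (89.5 against 25.7 CPM, 3.48-fold, adjusted p = 0.0370) rose. Treg core (camera adjusted p = 6.75e-06), interferon response (camera adjusted p = 6.42e-11) and STAT5 targets (camera adjusted p = 0.000300) fell and were kept with an estimated correlation. They had 3, 2 and 1 members lower, 10, 16 and 9 not passing, and 4, 10 and 3 lower adjusted over the list alone. Colon Treg and Th17 lost its call (higher, camera adjusted p = 0.00186, adjusted p = 0.0984 with an estimated correlation, 8 not passing, 2 higher adjusted over the list alone). Homing receptors lost theirs (higher, camera adjusted p = 0.0295, adjusted p = 0.0916 with an estimated correlation, 18 not passing, 1 higher adjusted over the list alone). So did immediate early and heat shock (lower, camera adjusted p = 0.000471, adjusted p = 0.0594 with an estimated correlation, Junb lower, 13 not passing, 4 lower adjusted over the list alone). Cholesterol synthesis was the last (lower, camera adjusted p = 0.0481, adjusted p = 0.402 with an estimated correlation, 14 not passing, 1 lower adjusted over the list alone). In all 7 genes rose and 23 fell. The count was 4, 10 and 6 without mice 1, 2 and 4, and 2 with only the 8 libraries of the gate, where 10 of 12 named genes lost the call. Of the 10 named genes only Junb, Il2ra and Gpr83 kept the call whichever mouse was left out, while Irf7 had adjusted p = 0.0501 without mouse 1 and 0.0608 without mouse 4.

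In TSLPR+ST2- Treg 7 genes passed. Higher in cancer were the tetraspanin Tspan13 (484 ± 36.6 against 319 ± 20.8 CPM, n = 4 each, 1.52-fold, edgeR adjusted p = 0.0280), H2-Q6 (1.39-fold), the Mediator kinase Cdk19 (2.68-fold) and Stip1 (1.39-fold). Lower were the histone methyltransferase Kmt2d (104 ± 11.9 against 203 ± 15.7 CPM, 1.94-fold, adjusted p = 0.0280), the N-terminal acetyltransferase Naa60 (1.83-fold) and Irf7 (1.65-fold). Every list call here was lost with an estimated correlation. Lower were Treg core (camera adjusted p = 0.000238, adjusted p = 0.0572 with an estimated correlation, 13 not passing, 1 lower adjusted over the list alone) and interferon response (camera adjusted p = 3.80e-07, adjusted p = 0.101 with an estimated correlation, Irf7 lower, 17 not passing, 6 lower adjusted over the list alone). Proliferation was lower (camera adjusted p = 2.43e-09, adjusted p = 0.0783 with an estimated correlation, 18 not passing, 3 lower adjusted over the list alone). Glycolysis was lower (camera adjusted p = 2.87e-05, adjusted p = 0.0706 with an estimated correlation, 15 not passing, 2 lower adjusted over the list alone), and so were STAT5 targets (camera adjusted p = 0.00373, adjusted p = 0.0728 with an estimated correlation, 10 not passing, 2 lower adjusted over the list alone). Immediate early and heat shock (camera adjusted p = 0.00425, adjusted p = 0.129 with an estimated correlation), Th2 (0.0123 and 0.129), cholesterol synthesis (0.00373 and 0.207) and TCR activation (0.00382 and 0.221) were lower. They had 14, 5, 14 and 13 members not passing and 3, 1, 1 and 0 lower adjusted over the list alone. Macrophage and dendritic markers were higher (camera adjusted p = 0.00313, adjusted p = 0.257 with an estimated correlation) with 14 not passing, also adjusted over the list alone. The count was 0 without mouse 1, 3, 4 or 7, 1 without mouse 2 or 8, 4 without mouse 5 and 18 without mouse 6, so no named gene here kept its call throughout. With only the 8 libraries of the gate 2 genes passed, both lower, and DESeq2 called 40 higher and 55 lower.

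In TSLPR+ST2+ Treg 247 genes were higher and 371 lower with cancer, while 17 passed with only the 8 libraries of this gate, against 21 in TSLPR-ST2- Treg fitted in the same way. With the log2 mitochondrial share as a covariate 4 passed, against 50 in TSLPR-ST2+ and 21 in TSLPR-ST2- Treg. DESeq2 turned the balance, with 679 higher and 633 lower, and RLE size factors gave 305 and 329. Totals in this gate were 4038718 to 5816224 counts in cancer and 6607867 to 8839946 in naive libraries, without overlap. Libraries were thinned to equal totals only for the per-mouse sums, so the effect of depth on these calls was not tested. Dusp5, a phosphatase that turns off ERK signalling (chromosome 19, 53529109 to 53542431, + strand), fell 3.29-fold from 163 ± 19.4 to 49.6 ± 7.36 CPM (n = 4 each, edgeR adjusted p = 1.82e-06). Junb (2.10-fold, adjusted p = 0.000108), Abcb9 (3.56-fold), the small nuclear RNA transcription factor Snapc4 (6.46-fold) and the dynein partner Dctn1 (3.16-fold) fell as well. Ddx17 rose 2.83-fold from 58.7 ± 5.34 to 166 ± 38.1 CPM (adjusted p = 2.52e-05), beside the actin-binding Tmsb4x (1.38-fold), the myosin light chain Myl12b (1.41-fold) and the microRNA silencing gene Tnrc6b (1.57-fold). The intestinal mucin Muc3 also passed, yet 1178 CPM in mouse 7 made up nearly all of its signal, and its adjusted p was 0.522 without that mouse and 0.0542 without mouse 3. Treg core fell (camera adjusted p = 0.00429, adjusted p = 0.1102 with an estimated correlation) with 5 lower, 1 higher and 7 not passing (6 lower and 1 higher adjusted over the list alone). Lrrc32 (73.0 ± 25.6 against 298 ± 132 CPM, 4.08-fold, adjusted p = 0.000200), Gpr83 (2.37-fold), the IL-2 receptor beta chain Il2rb (383 against 958 CPM, 2.50-fold) and Il2ra (1.60-fold) were lower.

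STAT5 targets fell in the same gate and kept the call with an estimated correlation (camera adjusted p = 0.000670, then 0.0457), with Il2ra, Socs2 and Socs3 lower, 7 not passing and 5 lower adjusted over the list alone. Interferon response fell (camera adjusted p = 1.51e-05, adjusted p = 0.172 with an estimated correlation) with Irf7 (1.60-fold) and Ifit3 (2.45-fold) lower, 16 not passing and 2 lower adjusted over the list alone. Homing receptors fell (camera adjusted p = 0.0312, adjusted p = 0.155 with an estimated correlation). Itgae, which pairs to bind E-cadherin (341 against 638 CPM, 1.87-fold), Itgb7 and S1pr1 were among the 4 lower genes, 14 did not pass and 5 were lower adjusted over the list alone. Th2 fell (camera adjusted p = 0.0134, adjusted p = 0.172 with an estimated correlation) with 5 not passing and 2 lower adjusted over the list alone. Epithelial markers were not called (camera adjusted p = 0.145), with 6 of 9 higher, 3 not passing, and 6 higher and 1 lower adjusted over the list alone. Epcam averaged 234 ± 285 CPM in the cancer libraries of this gate, 660.5 in mouse 7 against a mean of 91.7 in the other 3, and 144 ± 28.6 in the naive libraries. Krt8 was 820.4 CPM in mouse 7 and 4.26 to 17.1 in mice 5, 6 and 8, and the list had camera adjusted p = 0.3955 (direction higher) without the mouse 7 library. Mitochondrial genes made up 2.48 ± 0.775% of counts in the cancer libraries (2.83, 2.42, 3.23 and 1.43% in mice 5 to 8) and 0.865 ± 0.269% in the naive libraries. The share was also higher with cancer in TSLPR-ST2- (1.43 ± 0.146 against 1.04 ± 0.175%) and TSLPR+ST2- libraries (1.62 ± 0.236 against 1.12 ± 0.0537%), where cancer and naive ranges did not overlap, and was 1.25 ± 0.333 against 1.09 ± 0.318% in TSLPR-ST2+. With the log2 share as a covariate 0 of 35 called named genes of this gate kept the call, and Socs3 (log2 0.23), Itgb7 (log2 0.20), Tnfrsf1b (log2 0.12) and Muc3 (log2 -0.65) turned direction. With the 3 marker scores as covariates 89 genes passed. Leaving out mouse 2, 3, 4, 5 or 7 gave 369, 171, 187, 349 and 353 genes, and leaving out the mouse 7 library gave 337.

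**Figure D3:**
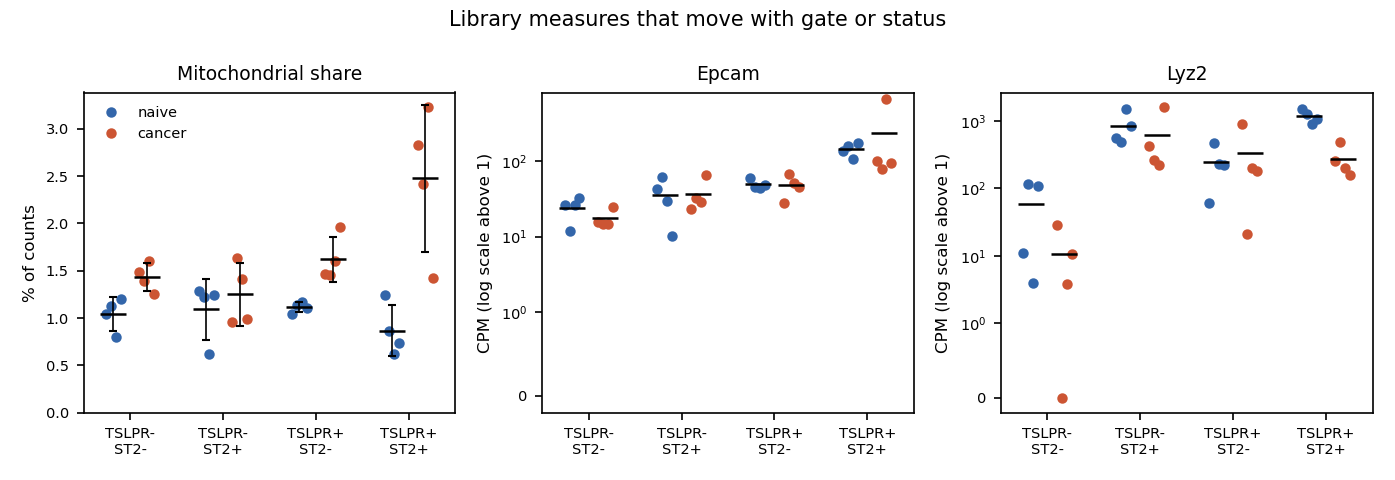
Mitochondrial share of counts (linear axis, mean ± SD) and CPM of Epcam and Lyz2 (logarithmic axis, means) in each Treg library by gate, naive blue and cancer orange (n = 4 mice per group).

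Effector tissue Treg genes were higher in ST2+ than in ST2- Treg, though, as given below, more of them were higher with TSLPR. Itgb1, the beta 1 integrin chain, was 3.42-fold higher in ST2+ than ST2- libraries (501 ± 187 against 141 ± 40.0 CPM, n = 16 each, 8 of 8 mice, edgeR adjusted p = 4.71e-10). Klrg1, an inhibitory receptor of terminal effector Treg, was 24.5-fold higher (390.4 ± 269 against 19.7 ± 20.2 CPM, adjusted p = 7.65e-08). Higher in 8 of 8 mice were also the inhibitory receptor Cd200r1 (2.70-fold), the calcium-binding S100a6 (2.32-fold) and S100a11 (1.90-fold), the transcription regulator Id2 (2.10-fold), Serinc3 (1.48-fold), Sh3bgrl (1.86-fold) and Cldnd1 (1.84-fold). Lower in 8 of 8 mice were the survival gene Bcl2 (303 ± 158 against 596 ± 175 CPM, 2.07-fold, adjusted p = 5.28e-07), Il2ra (1.48-fold, adjusted p = 1.40e-05) and Gpr83 (1.81-fold). So were Foxn3 (1.48-fold), the protease Ctsw (1.69-fold), the adhesion regulator Cytip (1.26-fold), the nuclease Rexo2 (1.49-fold), Ly6c1 (1.81-fold), the translation factor Eif5a (1.26-fold) and the phosphatase Inpp4b (1.34-fold). In all 550 genes rose and 347 fell, while limma-voom with the mouse as a random effect called 473 higher and 494 lower. Without mouse 3 or 4 the count was 459 or 570, and with the 3 marker scores it was 46.

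Effector tissue Treg genes rose (camera adjusted p = 1.59e-14, kept with an estimated correlation). Of 19 genes 8 rose, 11 did not pass and 10 were higher adjusted over the list alone. Il9r, the receptor for the mast cell growth factor IL-9, was 35.3 ± 10.7 against 2.47 ± 3.92 CPM (adjusted p = 4.58e-07). Its model estimate of 51.7-fold averages log2 changes over 4 pairs of groups, with 0 to 6.66 CPM in the ST2- groups. Next came Itgae (2.22-fold) and the nuclear receptor Rora (1.89-fold). Th2 rose (camera adjusted p = 0.000964, adjusted p = 0.0519 with an estimated correlation), with Gata3, the Th2 and ST2 regulator (133 ± 37.2 against 75.1 ± 16.4 CPM, 1.76-fold, adjusted p = 4.81e-05), and Il4 higher, 3 not passing and 4 higher adjusted over the list alone. STAT5 targets fell and were kept (camera adjusted p = 0.00224): 4 of 10 fell, 6 did not pass, also adjusted over the list alone, among them the lymphotoxin gene Lta (1.83-fold). Tumour-infiltrating Treg genes rose (camera adjusted p = 0.000111, adjusted p = 0.0861 with an estimated correlation) with Ebi3, a subunit of IL-35 (2.21-fold), and Icos (1.39-fold) higher, 9 not passing and 5 higher adjusted over the list alone. Homing receptors rose (camera adjusted p = 0.0110, adjusted p = 0.0597 with an estimated correlation) with 4 higher, 2 lower, 12 not passing, and 7 higher and 2 lower adjusted over the list alone. Gpr15, a receptor that takes T cells to the colon, rose (129 ± 54.6 against 59.1 ± 30.7 CPM, 2.35-fold, edgeR adjusted p = 1.42e-05), and the lymph node receptor Ccr7 fell. Ccr10 had no counts in any ST2- library. Naive and central T cell genes fell (camera adjusted p = 0.00766, adjusted p = 0.129 with an estimated correlation) with 4 lower, 7 not passing and the IL-7 receptor Il7r higher (1.67-fold). There were 5 lower and 1 higher adjusted over the list alone. Th1 rose (camera adjusted p = 0.0457, adjusted p = 0.129 with an estimated correlation) with Il18rap and Cxcr3 higher, 9 not passing and 3 higher adjusted over the list alone.

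Markers of other cells also differed by ST2. Macrophage and dendritic markers rose and were kept with an estimated correlation (camera adjusted p = 2.75e-11). Of 14 genes 9 rose, 5 did not pass, and 11 were higher and 1 lower adjusted over the list alone. Lysozyme Lyz2 was 749 ± 528 against 160.0 ± 233 CPM (7.79-fold, edgeR adjusted p = 0.000463), C1qa was 64.9 against 11.8 CPM, and Cd68 and Csf1r also rose. B and plasma cell markers (camera adjusted p = 0.0110, adjusted p = 0.287 with an estimated correlation) rose with Ighm higher, 8 not passing and 3 higher adjusted over the list alone. Epithelial markers (camera adjusted p = 0.0194, adjusted p = 0.321 with an estimated correlation) rose with Epcam (117 ± 171 against 34.6 ± 16.9 CPM) and Car1 higher, 7 not passing and 4 higher adjusted over the list alone.

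TSLPR+ Treg had higher transcripts of costimulatory and inhibitory receptors and lower Klf2 and S1pr1. Icos, the costimulator, was 1106 ± 228 against 459.9 ± 128 CPM (n = 16 each, 8 of 8 mice, 2.43-fold, edgeR adjusted p = 1.11e-11). Tigit, an inhibitory receptor for CD155, was 184 ± 46.8 against 45.9 ± 26.2 (4.34-fold, adjusted p = 1.69e-10) and Ctla4, which strips CD80 and CD86, was 938 ± 125 against 565 ± 63.6 (1.66-fold, adjusted p = 1.19e-10). Klf2, the factor that drives tissue exit genes (270 ± 38.5 against 500.1 ± 63.1 CPM, 1.86-fold, adjusted p = 1.11e-11), and its target S1pr1 (439 against 862 CPM, 1.98-fold) fell. Higher in 8 of 8 mice were also the actin capper Capg (1.76-fold), the redox gene Glrx (2.55-fold), the transcription factor Maf (2.61-fold), S100a11 (2.16-fold), Rilpl2 (2.07-fold), the cystatin Cst7 (2.07-fold) and Pdcd1, which encodes PD-1 (2.65-fold). Lower in 8 of 8 were Ly6c1 (2.79-fold), Cytip (1.38-fold), the actin regulator Evl (1.83-fold), Atp1b3 (1.45-fold), the glucocorticoid-induced Tsc22d3 (1.72-fold), Ripor2 (1.75-fold) and the diacylglycerol kinase Dgka (1.47-fold). In all 1185 genes rose and 811 fell. Without mouse 1 the count was 1303, and with the 3 marker scores it was 72.

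**Figure D4:**
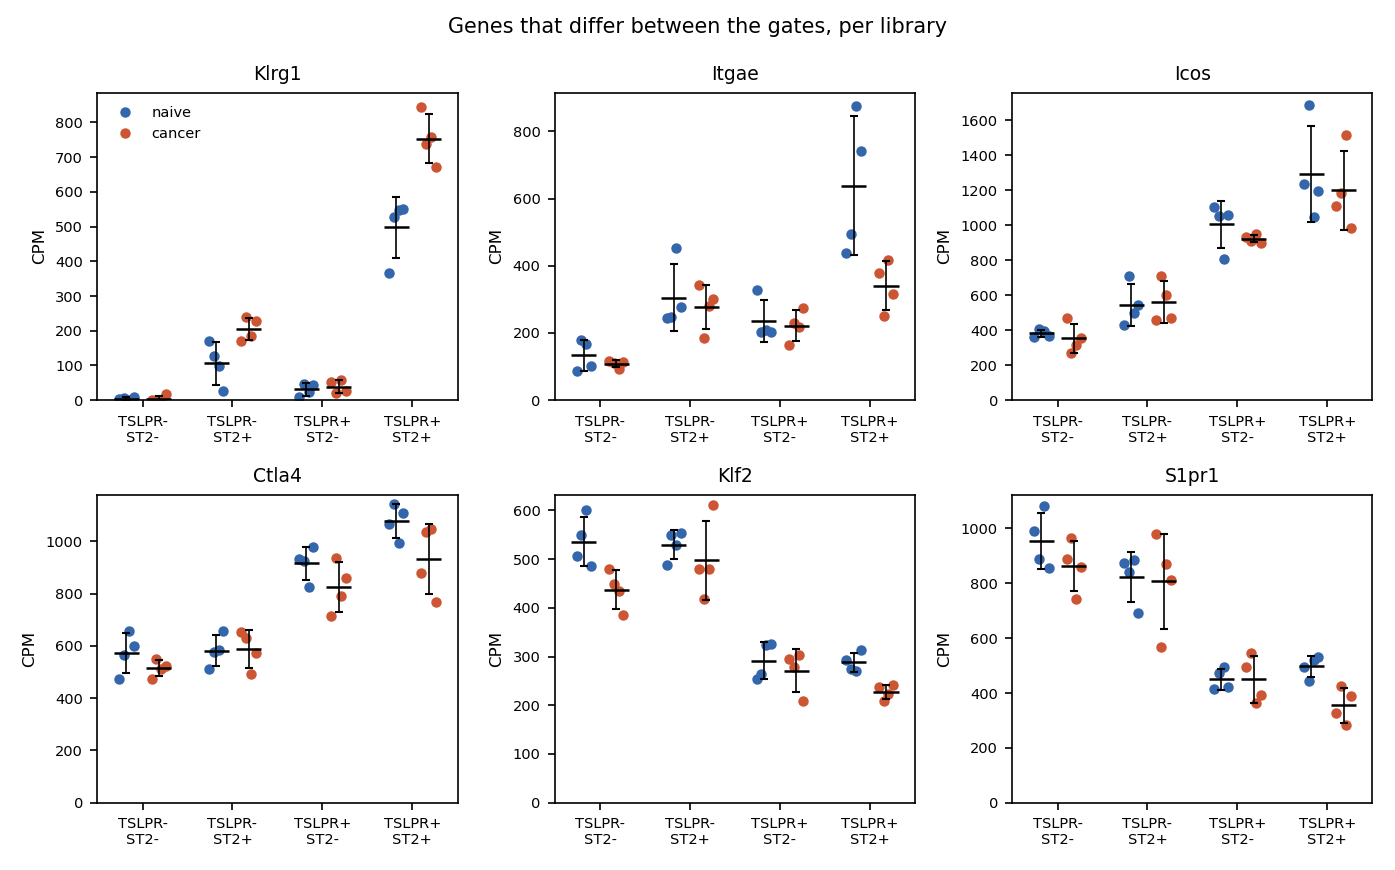
CPM of Klrg1, Itgae, Icos, Ctla4, Klf2 and S1pr1 by gate in naive (blue) and cancer (orange) mice, with each library as a point (n = 4 mice per group, mean ± SD).

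For TSLPR, 11 of 16 called lists kept the call with an estimated correlation. Tumour-infiltrating Treg genes rose (camera adjusted p = 1.38e-24). Here 11 of 11 rose, also adjusted over the list alone, among them the AP-1 factor Batf (1.64-fold). Effector tissue Treg rose (camera adjusted p = 3.50e-20, 15 higher, 4 not passing, 16 higher adjusted over the list alone). Inhibitory receptors and ectoenzymes rose (camera adjusted p = 2.62e-08, 7 higher, 4 not passing, 8 higher and 1 lower adjusted over the list alone), with the ATP-degrading Entpd1 1.71-fold higher. TNF receptor and CD28 family costimulation rose (camera adjusted p = 5.11e-06, 5 higher, 1 lower, 2 not passing, the same adjusted over the list alone), with the 4-1BB gene Tnfrsf9 at 479 against 239 CPM. Colon Treg and Th17 rose (camera adjusted p = 3.92e-07, 4 higher, 4 not passing, 8 higher adjusted over the list alone), with the aryl hydrocarbon receptor Ahr (2.51-fold) and Ccr6 (2.06-fold). Th1 rose (camera adjusted p = 0.00384, 4 higher, 7 not passing, the same adjusted over the list alone) with the chemokine Ccl5 (3.48-fold) and the chemokine receptor Cxcr3 (2.40-fold). Proliferation rose (camera adjusted p = 2.01e-09, 13 higher, 5 not passing, 18 higher adjusted over the list alone), with Mki67 at 44.4 ± 21.5 against 15.1 ± 16.1 CPM. Naive and central T cell genes fell (camera adjusted p = 5.82e-19, 9 lower, 3 not passing, 10 lower adjusted over the list alone), with Lef1 1.57-fold lower. STAT5 targets fell (camera adjusted p = 2.19e-06, 6 lower, 4 not passing, 8 lower adjusted over the list alone), with Bcl2 (1.87-fold), Osm (1.88-fold) and Socs3 (1.75-fold). B and plasma cell markers rose (camera adjusted p = 3.03e-06, 7 higher, 2 not passing, 7 higher adjusted over the list alone). Macrophage and dendritic markers rose (camera adjusted p = 6.36e-10, 12 higher, 2 not passing, 12 higher adjusted over the list alone), with the invariant chain Cd74 at 988 ± 722 against 199 ± 210 CPM.

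The remaining TSLPR list calls were lost with an estimated correlation. Interferon response fell (camera adjusted p = 8.45e-05, adjusted p = 0.124 with an estimated correlation) with 8 lower, 1 higher, 9 not passing, and 9 lower and 1 higher adjusted over the list alone. Gbp2, an interferon-induced GTPase, was 1.51-fold lower. Glycolysis rose (camera adjusted p = 0.00416, adjusted p = 0.105 with an estimated correlation) with 7 higher, 1 lower, 7 not passing, and 8 higher and 2 lower adjusted over the list alone. Its leading genes were Tpi1 (1.77-fold) and Gapdh (1.33-fold). Epithelial markers rose (camera adjusted p = 0.0218, adjusted p = 0.272 with an estimated correlation) with 4 higher, 5 not passing and 6 higher adjusted over the list alone, Epcam being 3.46-fold higher. Immediate early and heat shock genes were lower by the test (camera adjusted p = 0.0408, adjusted p = 0.193 with an estimated correlation, 4 lower, 10 not passing, also adjusted over the list alone) against a mean log2 change of 0.09. CD8, NK and gamma-delta markers were lower by the test (camera adjusted p = 0.0497, adjusted p = 0.0795 with an estimated correlation, and 0.0910 with the mouse as a block), against a mean log2 change of 0.06. They had 1 higher, 1 lower and 5 not passing, also adjusted over the list alone. Treg core was not called (camera adjusted p = 0.201): 6 rose, 4 fell, 3 did not pass, and 6 were higher and 6 lower adjusted over the list alone. TCR activation was not called either (camera adjusted p = 0.396): 1 rose, 1 fell, 11 did not pass, and 3 were higher and 1 lower adjusted over the list alone. Conventional helper cytokines were not called in any comparison (camera adjusted p = 0.723 here, with Il4 higher, Cd40lg lower and 2 not passing, also adjusted over the list alone). Of the lists too small to test, Csf3r (neutrophils) passed for ST2, Kit (mast cells) and Cxcr2 (neutrophils) for TSLPR, all under 6 CPM on average, and the endothelial Pecam1 was lower in TSLPR+ libraries (113 against 175 CPM).

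The 2 single-positive subsets differed from each other in the same mice. TSLPR+ST2- Treg held more Capg (1106 ± 79.2 against 607 ± 76.1 CPM, n = 8 each, 8 of 8 mice, 1.82-fold, edgeR adjusted p = 1.47e-08), Tigit (3.24-fold, adjusted p = 3.40e-05) and Ctla4 (1.49-fold). TSLPR-ST2+ Treg held more Itgb1 (607 ± 178 against 130 ± 32.9 CPM, 4.65-fold, adjusted p = 1.47e-08), Klf2 (514 against 281 CPM, 1.83-fold), S1pr1 (1.81-fold) and Gata3 (118 against 73.0 CPM, 1.61-fold, adjusted p = 0.0207). Also higher in TSLPR+ST2- were Gapdh (1.49-fold), Glrx (2.12-fold), the oxidoreductase Sccpdh (5.78-fold), the creatine kinase Ckb (2.20-fold), the epoxide hydrolase Ephx1 (1.61-fold), Neb (2.37-fold) and Susd3 (1.93-fold). Higher in TSLPR-ST2+ were the thioredoxin inhibitor Txnip (1.51-fold), Tsc22d3 (1.77-fold), Atp1b3 (1.44-fold), the phosphatase subunit Ppp2r5a (1.53-fold) and the cell cycle phosphatase Cdc25b (2.93-fold). Il1rl1 (60.0-fold lower, adjusted p = 1.84e-06) and Crlf2 (2.07-fold higher, adjusted p = 0.00107) followed the sort, and Foxp3 did not pass (138 against 131 CPM, adjusted p = 0.836). In all 208 genes were higher and 189 lower in TSLPR+ST2-, and the count was 216, 207, 249 and 219 without mice 1, 4, 5 and 8, and 249 with the 3 marker scores.

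For the single-positive comparison, 7 of 12 list calls were kept with an estimated correlation, with direction given for TSLPR+ST2-. Tumour-infiltrating Treg (camera adjusted p = 4.03e-16, 9 higher, 2 not passing, 10 higher adjusted over the list alone) and colon Treg and Th17 (camera adjusted p = 1.01e-08, 3 higher, 5 not passing, 6 higher adjusted over the list alone) rose. Inhibitory receptors and ectoenzymes rose (camera adjusted p = 1.37e-06, 5 higher, 6 not passing, 6 higher and 1 lower adjusted over the list alone). In the last of these, Lag3, an MHC class II ligand, was 30.7 against 3.65 CPM (8.12-fold, adjusted p = 0.00131). TNF receptor and CD28 family costimulation (camera adjusted p = 4.05e-05, 4 higher, 4 not passing, 6 higher and 1 lower adjusted over the list alone) and proliferation (camera adjusted p = 8.34e-10, 3 higher, 15 not passing, 11 higher adjusted over the list alone) rose. Treg core rose (camera adjusted p = 0.000730, 6 higher, 6 not passing, the same adjusted over the list alone), while Nrp1, a semaphorin receptor of Treg, was lower (175 against 338 CPM). Naive and central T cell genes fell (camera adjusted p = 3.00e-13, 6 lower, 6 not passing, 7 lower adjusted over the list alone). The call was lost for effector tissue Treg (higher, camera adjusted p = 0.00971, adjusted p = 0.134 with an estimated correlation, 6 higher, 3 lower, 10 not passing, 9 higher and 4 lower adjusted over the list alone). Interferon response lost its call (lower, camera adjusted p = 3.15e-05, adjusted p = 0.137 with an estimated correlation, 2 lower, 16 not passing, 7 lower and 1 higher adjusted over the list alone), and so did glycolysis (higher, camera adjusted p = 0.000730, adjusted p = 0.0774 with an estimated correlation, 4 higher, 11 not passing, 4 higher and 1 lower adjusted over the list alone). Cholesterol synthesis was lost (lower, camera adjusted p = 0.0412, adjusted p = 0.343 with an estimated correlation, Sc5d lower, 13 not passing, 1 lower adjusted over the list alone). B and plasma cell markers were lost too (higher, camera adjusted p = 0.00512, adjusted p = 0.2395 with an estimated correlation, 2 higher, 7 not passing, 2 higher adjusted over the list alone).

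No gene passed in the 3 interactions by edgeR's quasi-likelihood test. For ST2 by TSLPR the smallest adjusted p was 0.0768, for the CARF gene Cdkn2aip (log2 0.98, SE 0.18), with the adaptor Samsn1 (log2 0.87), the tetraspanin Cd81 (log2 0.83), Rexo2 (log2 -0.65) and the ciliary Drc1 next (adjusted p = 0.0993 each). There 1094 genes had unadjusted p under 0.05 (743 expected), DESeq2 called 120 and edgeR with the mouse as a block called 3. Cancer by ST2 had adjusted p = 0.444 for H2-Q6 (log2 -0.41), Ppm1l (log2 -2.11), Capn3 (log2 -1.05), Pde7b and Nr1h4, with 926 genes under unadjusted p 0.05 and 50 called by DESeq2. Cancer by TSLPR had adjusted p = 0.204 for the folate enzyme Mthfd1 (log2 -1.10), the TCR kinase Zap70 (log2 -0.55), Zfp940 and Txlnb and 0.387 for Naa60 (log2 -0.71), with 1178 genes under unadjusted p 0.05 and 58 called by DESeq2.

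Lists were called for ST2 by TSLPR in colon Treg and Th17 (lower, camera adjusted p = 0.000851), proliferation (lower, 0.000851), macrophage and dendritic markers (lower, 5.91e-07), glycolysis (lower, 0.00969), tumour-infiltrating Treg (higher, 0.0220), epithelial markers (higher, 0.0220) and TNF receptor and CD28 family costimulation (higher, 0.0424). With an estimated correlation their adjusted p were 0.165, 0.368, 0.165, 0.239, 0.368, 0.424 and 0.165 in that order. Adjusted over the list alone they had 0, 0, 3, 0, 2, 3 and 4 members passing (8, 18, 14, 15, 11, 9 and 8 not passing over all genes). For cancer by ST2 the calls were Treg core (lower, 0.0493), colon Treg and Th17 (higher, 0.0166), tumour-infiltrating Treg (higher, 0.0243) and proliferation (higher, 0.0166). Each was lost with an estimated correlation (adjusted p = 0.453, 0.453, 0.453 and 0.498), with 3, 2, 0 and 2 members passing adjusted over the list alone. For cancer by TSLPR they were inhibitory receptors and ectoenzymes (lower, 0.00956), interferon response (higher, 0.00956) and glycolysis (lower, 0.0106). They were also lost (adjusted p = 0.276, 0.572 and 0.276 with an estimated correlation), with 0 members passing adjusted over the list alone. No list member passed over all genes in an interaction.

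A contrast chosen after its values were seen set the cancer effect in TSLPR+ST2+ Treg against the mean of the other 3 gates, and 10 genes passed. Lower were Dctn1 (log2 -1.65, edgeR adjusted p = 0.00912), Dusp5 (log2 -1.22, adjusted p = 0.00912), H2-Q6 (log2 -0.60), Snapc4 (log2 -2.38), the zinc finger gene Unk (log2 -2.64), the class IIa deacetylase Hdac7 (log2 -1.12), and Zfp940, Drc1 and Rasl11b, which had no counts in the cancer TSLPR+ST2+ libraries. The kinase Sik2 was higher (log2 1.75, adjusted p = 0.0457). Other genes called in that gate alone are not shown to differ from the other gates. DESeq2 called 92 higher and 72 lower genes. The count was 3, 0, 5, 0, 4 and 24 without mice 1, 2, 3, 4, 5 and 8, and 0 with either covariate set.

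The single library of naive CD44low Foxp3-negative T cells had 0.282 CPM of Foxp3 (2 counts) against 109 to 221 CPM in 16 naive Treg libraries, and 10.2 CPM of Il2ra against 444 to 917. All 13 Treg core genes were below the naive Treg range. Of 12 naive and central T cell genes, 8 were above it, among them Ccr7, Tcf7 and Lef1, and 4 were within it.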

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

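Among the tests in this part, the chromosome, size-of-fall and covariate tests of the interferon list, all fits with covariates or with single libraries removed, the contrast of gates and the split counts other than that of the 618 genes were chosen only after the result was seen.

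The 618 genes that differed between cancer and naive TSLPR+ST2+ Treg could come from lower RNA quality, since the cancer libraries of mice 5 to 7 had a raised mitochondrial share. Mouse 8 (1.43%) was also above the naive libraries of this gate (0.618 to 1.24%), so it is not a clean comparison. Malat1, another library measure, was 957 to 1193 CPM in the cancer and 391 to 739 in the naive libraries of this gate. Its ranges were also apart in TSLPR-ST2- (967 to 1071 against 524 to 877) and TSLPR+ST2- (936 to 1053 against 674 to 808). They overlapped in TSLPR-ST2+ (601 to 1111 against 450 to 806). Whether this shift bears on the 618 genes or the interferon list was not tested. Genes called without mouse 8 and with part of the naive mice showed a median signed log2 difference of 0.571 in mouse 8 (between 0.173 and 0.987 over the choices), against 1.07, 1.12 and 0.849 when mice 5, 6 and 7 were the mouse left out, so this stays open. With the log2 mitochondrial share as a covariate 4 genes passed, the median log2 fold kept 0.350 of its size while the median SE went from 0.23 to 0.31, and 470 of 618 genes (76.1%) kept their sign. Epithelial cells in the mouse 7 library are argued against as the source of most of these genes. Without that library 94.2% of the genes kept their sign and 0.5 or more of their log2 fold. The genes were chosen with that library in the fit, which favours this result, and 14 of 35 called named genes lost the call without it. Chance is argued against, as 1 of 35 splits (the real one) gave as many genes. This is the lowest share that 35 splits can give, so chance is not excluded. The highest other split, which put mouse 8 with naive mice 2, 3 and 4, gave 108. The sort and sequencing days are not given in the sources used here, so a batch difference between naive and cancer mice cannot be told apart from the disease. Nor can effects of the AOM and DSS treatment. The cancer libraries of this gate also had lower totals than the naive ones, and whether depth adds to the calls was not tested. Lyz2 was lower in the cancer than in the naive libraries of this gate (278 ± 152 against 1200 ± 257 CPM), without overlap. Fewer macrophages, as doublets or stray RNA, could therefore add to the lower genes, and this stays open. With the 3 marker scores as covariates, 93.2% of the genes kept their sign and 0.5 or more of their log2 fold. The median SE went from 0.23 to 0.28, and 22 of 35 called named genes lost the call.

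The lower interferon list in cancer might follow RNA quality. Within groups the interferon score and the log2 mitochondrial share had r = -0.0753 (permutation p = 0.763, rho = 0.0473 with permutation p = 0.827, r without the 2 farthest libraries -0.00979, BH-adjusted p = 0.763). This r lies between the limits set beforehand, and a correlation within groups cannot decide a cause that acts between them. With that share as a covariate the list stayed lower in 4 of 4 gates (limma camera adjusted p = 3.25e-23, 4.02e-10, 2.64e-06 and 0.000172 at the preset correlation). Fewer macrophages in the cancer sorts, which the TCR+CD4+Foxp3+ gate would admit only as doublets or stray RNA, are left open by r = -0.0966 with their marker score (permutation p = 0.581, rho = -0.149 with permutation p = 0.438, r without the 2 farthest -0.121). This r met the limit set beforehand against that explanation, which asked only that the correlation not be positive. As a correlation within groups it cannot decide the matter either. The summed CPM in TSLPR-ST2- Treg fell 22.2 times as much for the interferon list (8143 to 5545) as for the macrophage markers (286 to 169). That gate had the least Lyz2 among the naive groups (a mean of 59.6 CPM, against 248 to 1200 in the other gates). The ratio was not computed in the other gates, so it does not speak for them. The list members lower per mouse lie on 8 chromosomes, so they do not all sit in 1 linked segment. Their positions cannot show whether a segment elsewhere changed them, so a linked segment stays open. Still, the call was lost with an estimated correlation in TSLPR+ST2- and TSLPR+ST2+ Treg and per mouse, so correlated genes could account for part of the evidence.

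Lyz2 and other macrophage genes in ST2+ Treg may come from macrophages or dendritic cells in the sorts, though the TCR+CD4+Foxp3+ gate would remove single cells of these types, which leaves doublets or stray RNA. The median of 10 such genes in ST2+ libraries was 11.03% of the Lyz2 mean, between the bounds set for and against, so this stays open. C1qa (64.9 CPM), C1qb (110.0), Csf1r (43.5) and Cd74 (849) were all measured there. With marker scores of macrophages, B cells and epithelial cells as covariates, the ST2 count fell from 897 to 46 and the TSLPR count from 1996 to 72. The median log2 folds kept 0.861 and 0.743 of their size while the median SE rose from 0.16 to 0.27 and from 0.14 to 0.27.

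Chance is argued against for these other counts above 0, since 1 split in each case (the real one) gave as many genes: 31 in TSLPR-ST2- (highest other 3), 30 in TSLPR-ST2+ (7), 7 in TSLPR+ST2- (0) and 186 per mouse (0), each of 35 splits. In the same way 1 labelling of 50 (the real one) gave as many: 897 for ST2 (186), 1996 for TSLPR (0) and 397 for the single-positive subsets (1). These are the lowest shares that 35 splits or 50 labellings can give, so chance is not excluded. The 7 genes of TSLPR+ST2- became 0 without mouse 1 and without the low-count filter. For the 10 genes of the contrast of gates, chosen after its values were seen, each split was given the gate with the most genes, and 1 of 35 splits (the real one) gave as many (highest other 2). Chance is argued against at the main setting, within the same limit of 35 splits, but the count was 0 without mouse 2 or 4 and with either covariate set. The interactions had 0 genes, so all 35 of 35 splits (highest other 1) or 50 of 50 labellings (highest other 2) give as many by construction, and this says nothing about chance.

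Of 154 checks for a library apart from its group, 15 stood out, where chance gives about 5%. The naive TSLPR-ST2+ library of mouse 3 was low in mitochondrial share (0.616%), ribosomal protein share (1.96%) and Malat1 (449.9 CPM). Il1rl1 was high in ST2- libraries of mouse 5 (7.80 CPM, TSLPR-ST2-) and mouse 6 (11.1 CPM, TSLPR+ST2-). Epcam stood out in the cancer TSLPR+ST2+ library of mouse 7 (660.5 CPM) and the cancer TSLPR-ST2- library of mouse 8 (25.1 CPM), and Muc3 in the TSLPR+ST2+ libraries of mouse 7 (1178 CPM) and the naive mouse 2 (0.421 CPM). Lyz2 was 1622 CPM in the cancer TSLPR-ST2+ library of mouse 8. Single named genes stood out for Emb (404.5 CPM, cancer TSLPR-ST2+ of mouse 6), Irf7 (765.0 CPM, naive TSLPR-ST2+ of mouse 4), Tspan13 (288 CPM, naive TSLPR+ST2- of mouse 2), Naa60 (83.0 CPM, naive TSLPR+ST2- of mouse 3) and Ddx17 (50.7 CPM, naive TSLPR+ST2+ of mouse 1). The cancer effect in TSLPR+ST2+ Treg differed from the mean of the other 3 gates for 10 genes, and for 0 genes with the log2 mitochondrial share as a covariate.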

How the results depend on the processing

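Fits with covariates and fits without single libraries in this part were chosen only after the results were seen. Of 5105 alternative estimates of named genes that passed in the main fit, 4190 kept the call, 905 were weaker and 10 reversed. Of 13548 that did not pass there, 287 passed. RLE size factors moved every count by less than 1.5 times. Counts moved by more than 1.5 times as follows, main count first. TSLPR-ST2- 31: DESeq2 142, marker scores 18, and 13, 14, 13, 18, 15 and 11 without mice 1, 2, 4, 5, 6 and 7 (at most 24, without mouse 3). TSLPR-ST2+ 30: DESeq2 242, voom with mouse 67, only the gate's libraries 2, mitochondrial covariate 50, marker scores 15, and 4, 10 and 6 without mice 1, 2 and 4. TSLPR+ST2- 7: no filter 0, DESeq2 95, voom 11, only the gate's libraries 2, and 0 without mouse 1, 3, 4 or 7, 1 without mouse 2 or 8, 4 without mouse 5 and 18 without mouse 6. TSLPR+ST2+ 618: no filter 358, DESeq2 1312, only the gate's libraries 17, mitochondrial covariate 4, marker scores 89, without the mouse 7 library 337, and 369, 171, 187, 349 and 353 without mice 2, 3, 4, 5 and 7 (at most 749, without mouse 8). Per mouse 186: DESeq2 1329, mean of gate contrasts 1001, thinned 314, mitochondrial covariate 0, and 69, 37, 98, 38, 79, 28, 57 and 67 without mice 1 to 8 in turn. ST2 897: marker scores 46, 459 without mouse 3 and 570 without mouse 4 (at most 783, without mouse 6). TSLPR 1996: marker scores 72, 1303 without mouse 1 (at most 1939, without mouse 6). Single-positive 397: DESeq2 857, voom 661, marker scores 249, and 216, 207, 249 and 219 without mice 1, 4, 5 and 8 (at most 527, without mouse 6). The 0 genes of ST2 by TSLPR became 120 with DESeq2, 3 with the mouse as a block, 8 with the mitochondrial covariate, 3 without the ST2+ libraries of mouse 5, 2 without mouse 3 or 5 and 1 without mouse 2 or 8. Cancer by ST2 gave 50 with DESeq2, and cancer by TSLPR 58 with DESeq2, 1 without the mouse 7 library and 1 without mouse 5. The contrast of gates went from 10 to 6 without a filter, 164 with DESeq2, 3 with voom, 0 with either covariate set, 3 without the ST2+ libraries of mouse 5, 3, 0, 5, 0, 4 and 24 without mice 1, 2, 3, 4, 5 and 8. The share of higher genes moved for DESeq2 from 23.3 to 46.3% in TSLPR-ST2+, from 57.1 to 42.1% in TSLPR+ST2-, from 40.0 to 51.8% in TSLPR+ST2+, from 23.7 to 40.9% per mouse and from 10.0 to 56.1% in the contrast of gates. It moved without a filter from 29.0 to 14.3% in TSLPR-ST2-, from 40.0 to 29.3% in TSLPR+ST2+ and from 10.0 to 0% in the contrast of gates, and with voom from 29.0 to 14.7% in TSLPR-ST2-, from 57.1 to 27.3% in TSLPR+ST2-, from 10.0 to 33.3% in the contrast of gates, from 61.3 to 48.9% for ST2 and from 52.4 to 63.2% for the single-positive subsets. With only a gate's libraries the 4 gates, in the order above, had 14.3, 0, 0 and 11.8% higher. The mitochondrial covariate gave 38.0, 80 and 0% in TSLPR-ST2+, TSLPR+ST2- and TSLPR+ST2+, marker scores gave 16.7% in TSLPR-ST2- and 24.7% in TSLPR+ST2+, and the mean of gate contrasts gave 34.2% per mouse. Without the ST2+ libraries of mouse 5 it was 37.5% in TSLPR+ST2- and 0% in the contrast of gates. Leaving out single mice also moved it by over 10 points within each gate, per mouse and in the contrast of gates. Estimated correlations took list calls from 5 to 3, 7 to 3, 10 to 0 and 5 to 1 in the 4 gates in the order above, from 10 to 0 per mouse, 10 to 3 for ST2, 16 to 11 for TSLPR and 12 to 7 for the single-positive subsets. They took 7, 4 and 3 to 0 for the interactions, where fry also called 0. The fry test called 13 per mouse. With the mouse as a block TSLPR kept 15 list calls (markers of CD8, NK and gamma-delta T cells lost, camera adjusted p = 0.0910) and ST2 by TSLPR gained Treg core (8 calls, camera adjusted p = 0.0286). Reversed were Tcrg-C2, cancer versus naive in TSLPR+ST2+ Treg, without mouse 8 (log2 0.00, against 7.19 without mouse 6) and in the same gate, with the mitochondrial covariate, Muc3 (-0.65), Tnfrsf1b (0.12), Itgb7 (0.20) and Socs3 (0.23). With marker scores Cd28 (0.011) and Car1 (-0.47) for ST2, and Car1 (-1.19), H2-Ab1 (-0.024) and Cxcr2 (-0.68) for TSLPR were reversed.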

Other observations

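Among the tests in this part, the fits with covariates and the neighbour count without mitochondrial and same-family pairs were chosen only after the result was seen.

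MHC class II genes were much higher in TSLPR+ libraries: H2-Aa 8.14-fold (367 against 51.3 CPM) and H2-Ab1 7.34-fold (529 against 86.4 CPM), as were the B cell genes Cd79b (2.59-fold) and Cd79a (5.49-fold). Doublets of Treg with antigen-presenting cells could give this, and with marker scores as covariates the log2 change of H2-Ab1 was -0.024, although those scores hold the gene itself. A test would be to sort the same gates with B cell and macrophage markers gated out.

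Genes called per mouse lie near each other on chromosomes more often than random sets, with 54 pairs within 1 Mb (random median 29, 95% limit 40, share of sets as high 0.0007). A linked segment that differs between the 2 sets of mice could do this, but without the mitochondrial genome and pairs of 1 gene family 25 pairs were left (random median 27, 95% limit 38, share of sets 0.67). Tandem families and mitochondrial genes could thus account for the excess. The 54 pairs nevertheless met the limit set beforehand for a linked segment. Of them 47 moved in the same direction, and 15 of the 54 were mitochondrial. A count over the whole genome cannot exclude a few segments, and same-family neighbours could themselves lie in one, so a linked segment stays open. Casp1 and Casp4 are 1 same-family pair of neighbours, and Casp4 was called in TSLPR-ST2+ Treg.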
